A study of Mus musculus with 8 samples.

How the data were processed

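Gene expression was profiled on 8 one-colour Illumina bead arrays labelled with Cy3, from mouse embryonic fibroblasts of the C57BL/6J strain grown in DMEM with fetal bovine serum, per the labels' protocols. RNA was extracted with an RNeasy column kit and its quality checked on a Bioanalyser, per the same protocols. The samples form 4 groups of 2 arrays: wild type untreated, wild type with 12 h of doxorubicin, staggerer untreated and staggerer with 12 h of doxorubicin. The doxorubicin dose, the scanner software and the tools used upstream are not given in the sources used here.

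The deposited non-normalized values are linear intensity values for 25697 probes and 1124 control rows, with no detection p beside them; 23074 blank rows were left out. A second table from the authors holds log2 values. It equals quantile normalization of the log2 deposited intensity with no background correction, as the largest difference was 5.1e-09. The series matrix was identical to that table (largest difference 0).

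The values were reprocessed from the intensities with limma 3.58.1 in R 4.3.3. The control rows carry no type, so they were taken as negative controls after 10 bright ones, over 5 median absolute deviations above the median, were left out, which left 1114. Background was corrected by the normal-exponential model fitted to these controls (nec, offset 16), followed by quantile normalization and log2. A probe's detection p was the share of control rows at or above its signal. Probes with a detection p under 0.01 on at least 2 of 8 arrays were tested, which kept 12362 probes. Of all probes, 23978 had 1 gene symbol, 0 had several and 1719 were unnamed here, and 23962 were matched to a current gene through their Entrez identifier. Each gene was represented by its brightest probe, which gave 9340 genes. Of these, 715 were unnamed probes, each kept as an entry of its own. They are part of every count and adjustment over genes, but none is named in the text. Values of other probes of a named gene are given where they differ by more than 1 on the log2 scale. Gene names come from the platform annotation and a RefSeq table of assembly GRCm38.p6, used for names and for neighbouring genes. As no genome build is named in the files, no coordinates are given. Values for Trp53 and Bax are not analysed here.

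A linear model with 1 mean per group was fitted to all 8 arrays (lmFit, eBayes), so that the 4 groups share 1 estimate of the spread, with 4 residual and 3.37 prior degrees of freedom. The 5 comparisons were the doxorubicin effect in each genotype, the genotype effect in each condition, and their interaction. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Adjusted p-values given for genes are from limma, and those for gene lists from its camera test. A gene undetected on both arrays of a group has only a bound there. It is given as "at least N-fold", the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among detected probes and its own. The interaction has no such bound for genes, and its values are fitted ones. Where the median of a called list moved by more than 0.1 with such members at their bound, both medians are given with the comparison; other list medians are fitted ones unless a bound is given. Without background correction the median was nearer to 0 for 46 of 46 calls of a list in a comparison.

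Before the data were examined, 34 gene lists (pathways, complexes and markers of other cell types a fibroblast culture could hold) were fixed from textbook knowledge, together with the design, the alternatives and the rule for named genes. The 28 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 140 tests, and again with an estimated correlation. With the estimated correlation 0 lists were called in any comparison, while 5, 3, 8, 4 and 5 lists had an unadjusted p under 0.05 in the order of the comparisons above. That test rests on only 4 residual degrees of freedom and has little power over 140 tests. A failure to call a list there therefore neither undoes nor upholds its call with the preset correlation. The rule named, in each comparison, the 10 genes with the largest rise and the 10 with the largest fall among those that passed, up to 4 members of each described list with the smallest p, and a fixed set of genes of the p53 pathway with Rora. The ribosomal protein list was matched by name and also took Rps6ka3, Rps6ka5, Rpl22l1, Rpl7l1, Rps19bp1 and Rps27l, which are not ribosomal proteins of the standard set.

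The alternatives fixed in advance were no background correction, median centring, the authors' table, no detection filter, detection on all 8 arrays, the mean of a gene's probes, a variance trend with robust hyperparameters, the replicate number as a block, a fold of at least 1.5, only the 4 arrays compared, an estimated correlation in camera, and leaving out each array. Chosen after seeing the data were no between-array normalization, leaving out both staggerer doxorubicin arrays, and detection on at least 1 array of a compared group. The steps were tested on simulated data in which 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold. Only the staggerer doxorubicin group was changed, with a gene's spread equal in all groups. With so few changed genes the adjusted threshold is stricter than in the real data. The recovered shares therefore do not give the power of the real tests. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.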

Results

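Messenger RNA was measured on 8 bead arrays in mouse embryonic fibroblasts, primary connective tissue cells grown from embryos. The cells were wild type or staggerer. Staggerer is a mouse mutation, a deletion within Rora, the gene of the nuclear receptor RORα. Cultures of each genotype were left untreated or given doxorubicin for 12 h. Doxorubicin is an anthracycline that poisons topoisomerase II and breaks DNA, and DNA damage activates the transcription factor p53. Each of the 4 groups had 2 arrays, and the design asks which responses to DNA damage differ between the genotypes. Fold changes are given on the log2 scale with their standard error (SE) from limma, and n is 2 arrays in every group. The labels do not say whether the 2 arrays of a group came from separate cultures, so the p-values measure only the spread between arrays, which may be technical. Nor do they say how many embryos or cell isolates stand for each genotype. A difference by genotype therefore cannot be told apart from one between isolates. Gene list medians are followed by their range over 4 scalings: quantile normalization, no background correction, median centring and no between-array normalization. The small number of arrays limits the precision of every value.

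The staggerer doxorubicin arrays stood apart from the others in signal. The number of detected probes was 11106.5 ± 67.2 (SD, n = 2) in untreated wild type cells, 11456.5 ± 163 in wild type cells after doxorubicin, 10964 ± 31.1 in untreated staggerer cells and 9411 ± 233 in staggerer cells after doxorubicin. The median background-corrected signal of the tested probes was 8.98 ± 0.19, 8.67 ± 0.02, 8.62 ± 0.01 and 7.60 ± 0.07 on the log2 scale in the same order, while the 99th percentile was 14.75 ± 0.19, 14.50 ± 0.00170, 14.44 ± 0.04 and 14.74 ± 0.03. The correlation between the 2 arrays of a group, across genes, was 0.9945, 0.9936, 0.9938 and 0.9826. Genes are not independent replicates, so these correlations carry no p-value.

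**Figure D1:**
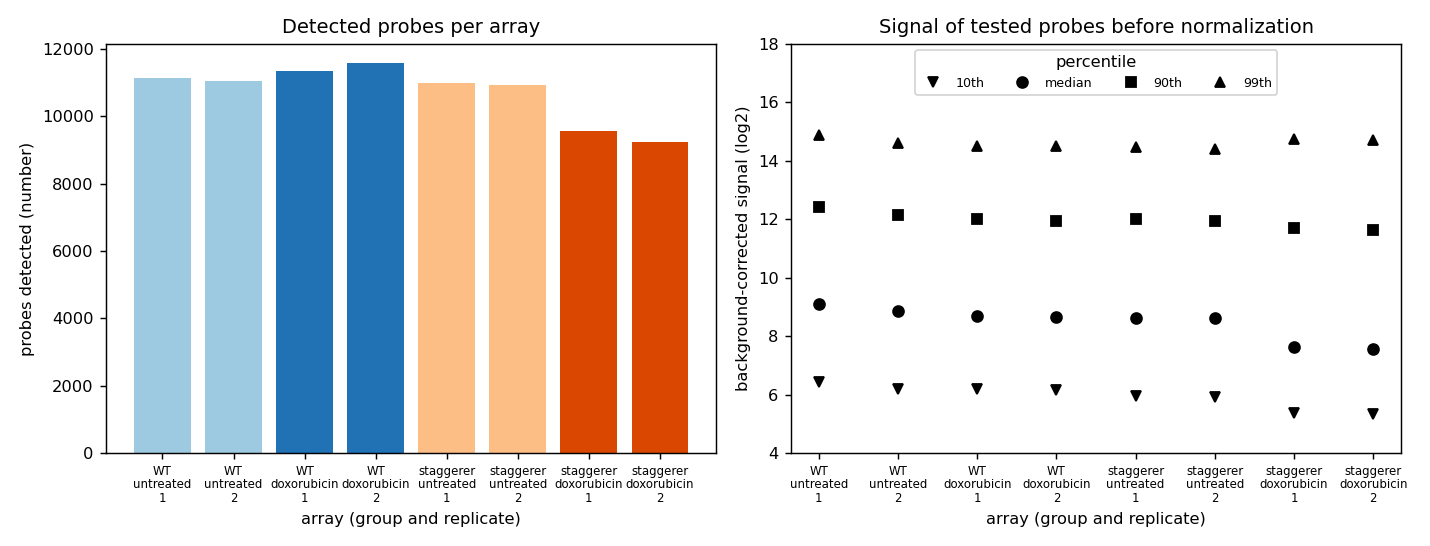
Left, the number of detected probes on each of the 8 arrays. Right, 4 percentiles, from the 10th to the 99th, of background-corrected log2 signal over the tested probes before between-array normalization, for the same arrays. The 2 staggerer doxorubicin arrays have fewer detected probes (mean 9411) and a lower median (7.60), with a 99th percentile (14.74) close to that of the untreated wild type arrays (14.75).

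Rora itself was measured by 1 probe above background. Its level was 7.90 ± 0.26 (SD, n = 2) in untreated wild type cells, 7.96 ± 0.05 in wild type cells after doxorubicin, 6.58 ± 0.01 in untreated staggerer cells and 6.41 ± 0.23 in staggerer cells after doxorubicin, where it was detected on 0 of 2 arrays. The position of the probe relative to the staggerer deletion was not determined, so this level is no check of the genotype labels. Rora was lower in untreated staggerer than in untreated wild type cells, by a log2 fold change of -1.32 ± 0.17 (limma adjusted p = 0.00237).

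What 12 h of doxorubicin changed in wild type fibroblasts was asked first. By camera with the preset correlation, lists of p53 targets, histones and interferon genes shifted up, with 22 of 31, 27 of 39 and 13 of 21 genes risen. Lists of DNA replication, cholesterol synthesis and extracellular matrix genes shifted down, with 18 of 29, 13 of 18 and 16 of 28 fallen. With an estimated correlation these lists had adjusted p-values from 0.181 to 0.33. Among the p53 targets, Pmaip1, which encodes the pro-apoptotic protein NOXA, rose by 2.94 ± 0.14 on the log2 scale (adjusted p = 7.9e-06). Mdm2, the ubiquitin ligase that targets p53 for degradation, rose by 0.97 ± 0.14 (adjusted p = 0.000821), and Cdkn1a, the cell cycle inhibitor p21, rose by 0.69 ± 0.13 (adjusted p = 0.00315). Top2a, which encodes the topoisomerase that doxorubicin poisons, fell by 2.91 ± 0.15 (adjusted p = 8.64e-06).

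Of 31 p53 targets tested, 22 rose, 0 fell and 9 did not pass, with a median of 0.61 (0.40 to 0.71 over the 4 scalings, camera adjusted p = 3.23e-05, and adjusted p = 0.181 with an estimated correlation); adjusted over the list alone, 22 rose. Tap1, an antigen peptide transporter, rose by 2.50 ± 0.16, the death receptor gene Fas by 1.96 ± 0.14 and Pidd1, a death domain adaptor, by 1.35 ± 0.13. Bbc3, which encodes the pro-apoptotic protein PUMA, had a log2 fold change of 0.03 ± 0.19 (adjusted p = 0.923). Usp7, a deubiquitinase acting on MDM2 and p53, had 0.19 ± 0.17 (adjusted p = 0.393), and Rora had 0.06 ± 0.17 (adjusted p = 0.793). Of 9 p53 targets with apoptotic functions, 6 rose and 0 fell (median 0.94, 0.57 to 0.94 over the 4 scalings, camera adjusted p = 0.0103, and adjusted p = 0.314 with an estimated correlation); adjusted over the list alone, 6 rose. Histone genes rose in 27 of 39 cases and fell in 8, while 4 did not pass (median 1.5, 1.06 to 1.5 over the 4 scalings, camera adjusted p = 3.23e-05, and adjusted p = 0.261 with an estimated correlation); adjusted over the list alone, 27 rose and 8 fell. H4c8 rose by 2.94 ± 0.12 and H2bc6 by 2.67 ± 0.13. The 8 that fell were all H2A genes. A probe can read several near-identical histone genes, so the count of histone genes is uncertain in every comparison. Of 21 interferon response genes, 13 rose, 2 fell and 6 did not pass (median 1.0, 0.42 to 1.21 over the 4 scalings, or 0.63 with members undetected in a group at their bound; camera adjusted p = 0.00144, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 13 rose and 2 fell. Usp18, which removes the ubiquitin-like modifier ISG15, rose by 3.49 ± 0.12, and the immunoproteasome subunit gene Psmb9, detected on 1 of 2 untreated wild type arrays, rose by 2.95 ± 0.17.

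Other groups of genes fell in wild type cells. Of 29 DNA replication genes, 18 fell, 4 rose and 7 did not pass (median -0.79, -1.11 to -0.51 over the 4 scalings, camera adjusted p = 0.0113, and adjusted p = 0.33 with an estimated correlation); adjusted over the list alone, 18 fell and 4 rose. The polymerase δ subunit gene Pold1 had -2.28 ± 0.12 and the ribonucleotide reductase gene Rrm1 had -2.01 ± 0.11. Cholesterol synthesis genes fell in 13 of 18 cases and rose in 1, while 4 did not pass (median -0.96, -1.24 to -0.80 over the 4 scalings, camera adjusted p = 0.00503, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 13 fell and 2 rose. The sterol carrier gene Stard4 fell by 1.67 ± 0.11 and Hmgcs1, an early enzyme of the pathway, by 1.34 ± 0.11. Ribosome biogenesis genes fell in 10 of 15 cases and rose in 0 (median -0.64, -0.92 to -0.52 over the 4 scalings, camera adjusted p = 0.00503, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 11 fell. The nucleolar protein genes Nop58 and Gnl3 had -1.42 ± 0.17 and -1.23 ± 0.12. Extracellular matrix genes fell in 16 of 28 cases and rose in 0 (median -0.39, -0.67 to -0.36 over the 4 scalings, camera adjusted p = 0.00912, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 16 fell. Elastin (Eln) had -2.72 ± 0.14 and the microfibril gene Mfap5 had -1.82 ± 0.12. Contractile smooth muscle genes fell in 8 of 12 cases and rose in 0 (median -0.58, -0.82 to -0.51 over the 4 scalings, camera adjusted p = 0.0154, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 8 fell. Mylk, myosin light chain kinase, had -2.71 ± 0.16 and the actin nucleator gene Lmod1 had -2.56 ± 0.13. Fibroblast markers fell in 7 of 12 cases and rose in 0 (median -0.59, -0.87 to -0.26 over the 4 scalings, camera adjusted p = 0.0284, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 7 fell. The growth factor receptor gene Pdgfrb had -2.17 ± 0.14.

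Across all 9340 genes tested, 5304 changed in wild type cells, 2465 up and 2839 down, of which 2423 changed at least 2-fold. Several of the genes with the largest rises were below background in untreated cells, so their rise is a bound. Cited4, a transcriptional coactivator, was at least 60.1-fold higher (adjusted p = 2.18e-06), the matrix gene Matn4 at least 58.9-fold, Mreg at least 33.7-fold, the potassium channel gene Kcnc4 at least 25.9-fold, Slc23a3 at least 25.6-fold, Ankk1 at least 17.2-fold and the actin-severing protein gene Scin at least 14.3-fold. Amer2 and S100a7a, each detected on 1 of 2 untreated arrays, rose by 5.48 ± 0.23 and 5.32 ± 0.13, and the sterol hydroxylase gene Cyp27a1 rose by 5.29 ± 0.19. Other probes gave 1.84 for Kcnc4, 3.10 and 2.73 for Matn4, 3.94 for Amer2 and 6.87 for Cyp27a1. The largest falls included Ccn5 (-3.42 ± 0.16), the muscle ankyrin repeat protein gene Ankrd1 (-3.25 ± 0.13), the chemokine gene Cxcl12 (-3.20 ± 0.14), Rgs4 (-3.12 ± 0.32), Cyp7b1 (-2.96 ± 0.41, detected on 1 of 2 treated arrays), Fignl1 (-2.95 ± 0.18) and Angptl7 (-2.90 ± 0.19). Hspa12b was at least 6.0-fold and the homeobox gene Meox1 at least 3.87-fold lower. With no between-array normalization, the median of all genes was -0.35 and 30.5% of the changed genes rose, against 46.5% with quantile normalization.

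What the same treatment changed in staggerer fibroblasts was asked next. Here the p53 targets were not called as a list. Lists of ribosome biogenesis and clock genes shifted down by camera with the preset correlation, with 12 of 15 and 8 of 12 genes fallen, and those of oxidative phosphorylation, ribosomal proteins and histones shifted up, with 35 of 74, 18 of 58 and 25 of 39 risen. With an estimated correlation these had adjusted p-values from 0.251 to 0.391. Of all 9340 genes 2964 rose and 3108 fell. The ribosomal protein genes thus rose at about the share of all genes, and what set them apart was that only 2 of 58 fell. Those 2 were Rps15a and Rps19bp1, and the latter is not a ribosomal protein gene. Cdkn1a fell by 1.80 ± 0.13 (adjusted p = 3.53e-05), Mdm2 by 1.59 ± 0.14 (adjusted p = 7.21e-05) and Bbc3 by 2.52 ± 0.19 (adjusted p = 4.18e-05), while Pmaip1 rose by 1.57 ± 0.14 (adjusted p = 8.57e-05). These changes were measured on arrays whose median signal was 7.60 after doxorubicin against 8.62 before it. The 99th percentile was 14.74 against 14.44, so the bright end did not fall with the median. Whether the lists that shifted up did so through their level of expression was not tested.

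The median of the 31 p53 targets was -0.33, or -1.01 to 0.01 over the 4 scalings, with 7 up, 14 down and 10 not passing (camera adjusted p = 0.494, and adjusted p = 0.548 with an estimated correlation); adjusted over the list alone, 8 rose and 14 fell. Phlda3, an inhibitor of AKT signalling, fell by 1.87 ± 0.13. Usp7 fell by 0.64 ± 0.17 (adjusted p = 0.0137), and Rora, undetected on both treated arrays, did not pass (adjusted p = 0.388), with no size given. Another probe of Bbc3, detected on 3 of the 8 arrays, gave -0.41. Of 15 ribosome biogenesis genes, 12 fell, 2 rose and 1 did not pass (median -1.23, -1.86 to -0.80 over the 4 scalings, or -1.03 with undetected members at their bound; camera adjusted p = 0.00752, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 12 fell and 2 rose. Nip7 had -2.01 ± 0.15 and Gnl3 -1.99 ± 0.12. Clock genes fell in 8 of 12 cases and rose in 0 (median -0.85, -1.62 to -0.41 over the 4 scalings, camera adjusted p = 0.0154, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 8 fell. The clock repressor genes Bhlhe40 and Nfil3 had -2.02 ± 0.20 and -1.76 ± 0.14. Histone genes rose in 25 of 39 cases and fell in 8 (median 0.95, 0.44 to 1.47 over the 4 scalings, or 0.84 with undetected members at their bound; camera adjusted p = 0.00775, and adjusted p = 0.391 with an estimated correlation); adjusted over the list alone, 25 rose and 8 fell. Among those that fell were the histone H2A genes H2ac24 (-2.42 ± 0.14) and H2ac10 (-1.96 ± 0.12).

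Oxidative phosphorylation genes rose in 35 of 74 cases and fell in 9 (median 0.33, 0.26 to 1.28 over the 4 scalings, camera adjusted p = 0.00912, and adjusted p = 0.391 with an estimated correlation); adjusted over the list alone, 35 rose and 8 fell. The complex I assembly factor genes Ndufaf4 (-2.08 ± 0.14) and Ndufaf1 (-1.78 ± 0.17) were among those that fell. Ribosomal protein genes rose in 18 of 58 cases and fell in 2 (median 0.21, 0.20 to 1.45 over the 4 scalings, camera adjusted p = 0.0269, and adjusted p = 0.338 with an estimated correlation); adjusted over the list alone, 13 rose and 2 fell. Rps3a1 rose by 1.06 ± 0.11, and Rps19bp1, which encodes a binding partner of a ribosomal protein, was at least 1.41-fold lower. Macrophage markers rose in 5 of 6 cases and fell in 0 (median 1.01, 0.20 to 1.23 over the 4 scalings, camera adjusted p = 0.024, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 5 rose. Fcer1g, an Fc receptor subunit, rose by 1.20 ± 0.14 and lysozyme (Lyz2) by 0.91 ± 0.12. The macrophage call was lost without background correction (median 0.67, adjusted p = 0.0513) and with median centring (median 1.23, adjusted p = 0.0761). The interferon response genes had 6 up and 6 down of 21 (median -0.01, -0.17 to 0.85 over the 4 scalings, or 0.65 with undetected members at their bound; mean 0.16, camera adjusted p = 0.838). Of 25 immediate early genes 7 rose and 16 fell (median -0.92, -1.63 to -0.60 over the 4 scalings, or -0.65 with undetected members at their bound; camera adjusted p = 0.0523). That list was called down without background correction (adjusted p = 0.0184) and with median centring (adjusted p = 0.0157). In it, Klf2, a growth-restraining transcription factor, was at least 6.37-fold lower, the matricellular gene Ccn1 fell by 3.99 ± 0.18 and Klf6 fell by 3.04 ± 0.11, where another Klf6 probe gave -1.97. The extracellular matrix list, not called here (median 0.19, 0.16 to 1.19 over the 4 scalings, camera adjusted p = 0.247), was called up with median centring (median 1.19, adjusted p = 0.000543).

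In staggerer cells 6072 genes changed, 2964 up and 3108 down, of which 3054 changed at least 2-fold. Cited4 was at least 13.4-fold higher, Nrarp, a feedback inhibitor of Notch, at least 9.61-fold, Krtap1-5 at least 9.28-fold, the homeobox gene Gbx2 at least 8.46-fold, Kcnc4 at least 7.24-fold, the immediate early gene Egr4 at least 6.88-fold, Slc23a3 at least 6.79-fold, the POU factor gene Pou3f1 at least 5.85-fold and Nrip3 at least 5.31-fold. The mitochondrial protein gene Chchd10 rose by 3.90 ± 0.13. Cebpb, a transcription factor of inflammation and adipogenesis, fell by 4.07 ± 0.23 (adjusted p = 1.64e-05), and Plekhf1, detected on 1 of 2 treated arrays, by 3.70 ± 0.55, where another Plekhf1 probe gave -1.18. A second Kcnc4 probe gave 0.13. Zfpm2 was at least 7.18-fold lower, Rabif at least 6.38-fold, Pak4 at least 5.36-fold, Ctdspl at least 5.22-fold, Tefm at least 4.08-fold and Tmem186 at least 3.54-fold. The share of changed genes that rose was 48.8% with quantile normalization, 66.4% with median centring, where the median of all genes was 0.45, and 16.5% with no between-array normalization, where that median was -0.57. In simulated data for this comparison, 20.9% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 93.9% of those changed 4-fold were recovered among 9340 genes. Far fewer genes were changed in that simulation than passed here, so these shares are not the power of the real test.

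The responses of the 2 genotypes, which share no arrays, correlated across the 9340 genes with a Pearson r of 0.38 and a Spearman rho of 0.303; genes are not independent replicates. In both genotypes 1098 genes rose, against 782.3 for independent lists, and 1334 fell, against 944.7. Another 500 genes rose in wild type and fell in staggerer cells (820.3 for independent lists), and 665 did the opposite (900.9).

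**Figure D2:**
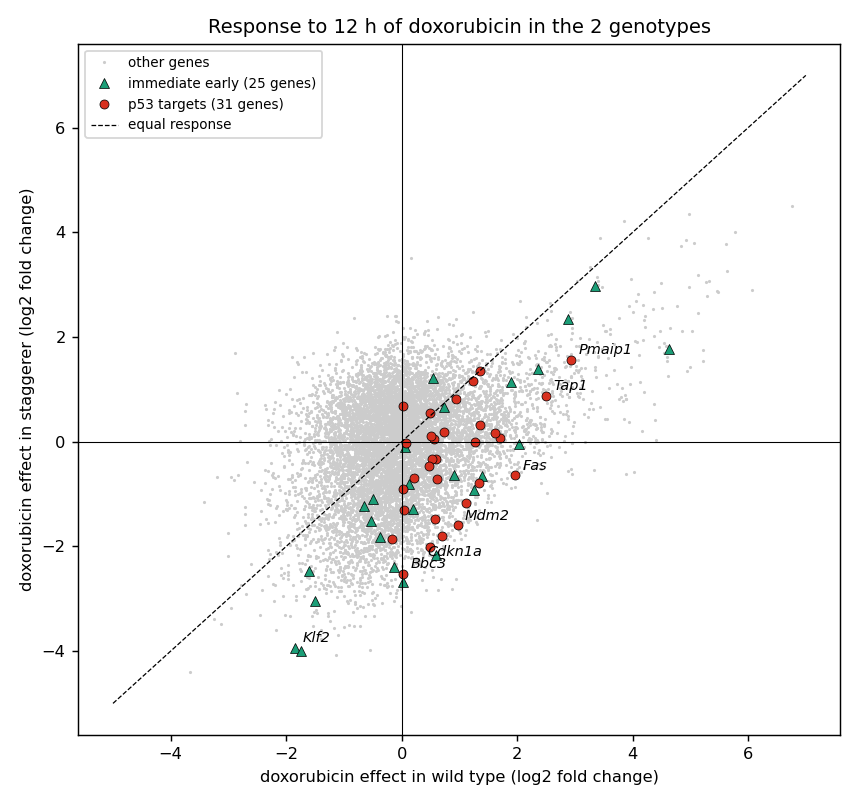
Each point is a gene, with its log2 fold change after 12 h of doxorubicin in wild type cells on the horizontal axis and in staggerer cells on the vertical axis, as fitted values with no bound for undetected genes. The 31 p53 targets (circles) and 25 immediate early genes (triangles) lie mostly below the dashed line of equal response, with Mdm2 at 0.97 and -1.59.

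How the genotypes differed before treatment was asked with the untreated arrays. By camera with the preset correlation, lists of DNA replication, mitotic and cholesterol synthesis genes and of macrophage and epithelial markers were shifted down in untreated staggerer cells, with 12 of 29, 3 of 19, 7 of 18, 4 of 6 and 4 of 6 genes lower. The histone list was shifted up, with 18 of 39 higher. With an estimated correlation these had adjusted p-values from 0.181 to 0.314. The platelet chemokine gene Ppbp was higher by 7.13 ± 0.16 on the log2 scale (adjusted p = 2.19e-06), and Mdk, the heparin-binding growth factor midkine, was lower, with a log2 fold change of -4.70 ± 0.11 (adjusted p = 2.19e-06). The uroplakin gene Upk3b was lower by at least 16.7-fold, the keratin gene Krt14 by at least 6.44-fold and the transcription factor gene Wt1 by at least 5.01-fold, and the uroplakin gene Upk1b had -3.86 ± 0.20. Another Upk3b probe gave -2.75.

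Of 29 DNA replication genes, 12 were lower, 0 higher and 17 did not pass (median -0.52, -0.88 to -0.38 over the 4 scalings, camera adjusted p = 5.29e-07, and adjusted p = 0.181 with an estimated correlation); adjusted over the list alone, 20 were lower. Mcm10 had -0.93 ± 0.14 and Rrm1 -0.88 ± 0.11. Of 19 mitotic genes 3 were lower and 0 higher (median -0.40, -0.74 to -0.30 over the 4 scalings, camera adjusted p = 0.00016, and adjusted p = 0.181 with an estimated correlation); adjusted over the list alone, 11 were lower. Top2a had -0.81 ± 0.15 and the mitotic kinase gene Plk1 -0.81 ± 0.18. Of 19 DNA repair genes 6 were lower and 1 higher (median -0.39, -0.71 to -0.21 over the 4 scalings, camera adjusted p = 0.032, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 6 were lower and 1 higher. The uracil glycosylase gene Ung had -0.91 ± 0.15 and the helicase gene Blm -0.67 ± 0.12. Histone genes were higher in 18 of 39 cases and lower in 3 (median 0.46, 0.10 to 0.46 over the 4 scalings, or 0.34 with undetected members at their bound; camera adjusted p = 0.00016, and adjusted p = 0.314 with an estimated correlation); adjusted over the list alone, 21 were higher and 8 lower. H4c8 had 1.59 ± 0.12 and H2bc6 1.32 ± 0.13. Cholesterol synthesis genes were lower in 7 of 18 cases and higher in 0 (median -0.52, -0.82 to -0.38 over the 4 scalings, camera adjusted p = 8.2e-05, and adjusted p = 0.181 with an estimated correlation); adjusted over the list alone, 10 were lower. Cyp51, a sterol demethylase gene, had -0.79 ± 0.13 and Stard4 -0.77 ± 0.11.

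Macrophage markers were lower in 4 of 6 cases and higher in 0 (median -1.72, -2.61 to -1.38 over the 4 scalings, or -1.60 with undetected members at their bound; camera adjusted p = 8.44e-05, and adjusted p = 0.181 with an estimated correlation); adjusted over the list alone, 4 were lower. Fcer1g had -2.58 ± 0.14 and Lyz2 -2.06 ± 0.12. Of 6 epithelial markers 4 were lower and 1 higher, and all 6 were undetected on every array of a group (median -1.30, -1.82 to -0.51 over the 4 scalings, or -0.74 at their bounds; camera adjusted p = 0.015, and adjusted p = 0.264 with an estimated correlation); adjusted over the list alone, 4 were lower and 1 higher. Krt18 was at least 1.43-fold lower. The epithelial call was lost with no between-array normalization (median -1.82, adjusted p = 0.0582). Fibroblast markers were lower in 4 of 12 cases and higher in 0 (median -0.34, -0.69 to -0.13 over the 4 scalings, or -0.11 with undetected members at their bound; camera adjusted p = 0.0255, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 4 were lower. Pdgfra, detected on 1 of 2 staggerer arrays, had -1.88 ± 0.20 and Fap, a serine protease of activated fibroblasts, was at least 1.66-fold lower.

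Interferon response genes were lower in 8 of 21 cases and higher in 1 (median -0.41, -0.74 to -0.29 over the 4 scalings, or -0.10 with undetected members at their bound; camera adjusted p = 0.0062, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 10 were lower and 2 higher. Usp18 had -1.83 ± 0.12, and Ifit3, an interferon-induced antiviral gene, was the higher member with 1.68 ± 0.11. Of 20 genes of the ATF4 and unfolded protein responses, 2 were lower and 0 higher (median -0.32, -0.61 to -0.23 over the 4 scalings, camera adjusted p = 0.000808, and adjusted p = 0.181 with an estimated correlation), as they were when adjusted over the list alone. Both were genes of serine and glycine metabolism, Psat1 (-0.70 ± 0.13) and Shmt2 (-0.70 ± 0.12). Ribosome biogenesis genes were lower in 2 of 15 cases and higher in 0 (median -0.37, -0.67 to -0.27 over the 4 scalings, camera adjusted p = 0.00812, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 4 were lower. The 2 were the nucleolin gene Ncl (-0.62 ± 0.13) and the fibrillarin gene Fbl (-0.47 ± 0.11). The p53 targets had a median of 0.10, or -0.24 to 0.13 over the 4 scalings, with 3 higher, 1 lower and 27 not passing (camera adjusted p = 0.316). Fas (1.10 ± 0.14, adjusted p = 0.00261) and Pmaip1 (0.69 ± 0.14, adjusted p = 0.021) were higher and Bbc3 was lower (-0.74 ± 0.19, adjusted p = 0.0469). Cdkn1a (0.01 ± 0.13, adjusted p = 0.983), Mdm2 (0.11 ± 0.14, adjusted p = 0.664) and Usp7 (-0.19 ± 0.17, adjusted p = 0.533) did not pass.

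In all, 1196 genes differed between the genotypes before treatment, 619 higher and 577 lower in staggerer cells, of which 472 differed at least 2-fold. Cxcl15 (4.68 ± 0.25) and the hypertrophic cartilage collagen gene Col10a1 (4.15 ± 0.20) were each detected on 1 of 2 wild type arrays. Reln, a secreted protein of neuronal positioning, was at least 7.25-fold, the glutamate transporter gene Slc1a1 at least 5.6-fold and Wfdc1 at least 5.34-fold higher. Igfbp2, which binds insulin-like growth factors, had 3.61 ± 0.12, Galnt13 2.84 ± 0.17, Pgam2 2.80 ± 0.19 and Abi3bp 2.63 ± 0.16, where another Abi3bp probe gave 0.53. Another Slc1a1 probe gave 1.91. Among lower genes, the retinoid-binding protein gene Crabp1 had -3.94 ± 0.19, Fxyd6 -3.68 ± 0.14, the chemokine gene Ccl4 -3.10 ± 0.13 and Chchd10 -3.07 ± 0.13, and Vat1l was at least 5.34-fold lower. Leaving out an array moved the number of genes to 518 (without untreated wild type replicate 1), 526 (without untreated wild type replicate 2), 590 (without untreated staggerer replicate 1) or 545 (without untreated staggerer replicate 2). With no between-array normalization the number was 2543, of which 11.8% were higher against 51.8% with quantile normalization, and the median of all genes was -0.34; with no detection filter it was 793.

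How the genotypes differed after 12 h of doxorubicin was asked with the treated arrays. By camera with the preset correlation, lists of p53 targets, immediate early, interferon and clock genes were shifted down in staggerer cells, with 24 of 31, 19 of 25, 17 of 21 and 10 of 12 genes lower. Those of matrix, contractile and oxidative phosphorylation genes were shifted up, with 16 of 28, 9 of 12 and 33 of 74 higher. With an estimated correlation these had adjusted p-values from 0.181 to 0.391. Bbc3 had a log2 fold change of -3.29 ± 0.19 (adjusted p = 1.21e-05), Cdkn1a -2.49 ± 0.13 (adjusted p = 1.01e-05), Mdm2 -2.45 ± 0.14 (adjusted p = 1.17e-05), Usp7 -1.01 ± 0.17 (adjusted p = 0.00123) and Pmaip1 -0.68 ± 0.14 (adjusted p = 0.00348). Another Bbc3 probe gave -0.41. Rora was at least 2.27-fold lower. These groups were measured on arrays with 9411 ± 233 (SD, n = 2) detected probes in staggerer and 11456.5 ± 163 in wild type cells. No comparison with genes of like level was made for the lists named here.

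Of the 31 p53 targets 24 were lower, 1 higher and 6 did not pass (median -1.21, -2.16 to -0.85 over the 4 scalings, camera adjusted p = 0.00174, and adjusted p = 0.181 with an estimated correlation); adjusted over the list alone, 24 were lower and 1 higher. Apaf1, the core of the apoptosome, had -2.42 ± 0.14. The 9 p53 targets with apoptotic functions had a median of -1.18 (-2.15 to -0.84 over the 4 scalings, camera adjusted p = 0.114). Immediate early genes were lower in 19 of 25 cases and higher in 1 (median -1.19, -2.07 to -0.88 over the 4 scalings, or -1.07 with undetected members at their bound; camera adjusted p = 0.00144, and adjusted p = 0.181 with an estimated correlation); adjusted over the list alone, 19 were lower and 1 higher. Dusp1, a phosphatase of MAP kinases, had -2.10 ± 0.12 and Junb, a subunit of AP-1, -1.94 ± 0.11. Interferon response genes were lower in 17 of 21 cases and higher in 2 (median -1.42, -2.14 to -0.75 over the 4 scalings, or -0.78 with undetected members at their bound; camera adjusted p = 0.00393, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 17 were lower and 2 higher. Usp18 had -3.09 ± 0.12 and Isg15 -2.38 ± 0.14. Clock genes were lower in 10 of 12 cases and higher in 0 (median -1.07, -2.05 to -0.64 over the 4 scalings, camera adjusted p = 0.0367, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 10 were lower. Bhlhe40 had -2.43 ± 0.20 and Nfil3 -2.07 ± 0.14.

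Extracellular matrix genes were higher in 16 of 28 cases and lower in 4 (median 0.44, 0.43 to 1.62 over the 4 scalings, camera adjusted p = 0.0186, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 16 were higher and 4 lower. Mfap5 had 4.13 ± 0.12 and the proteoglycan gene Lum 2.69 ± 0.11. Contractile genes were higher in 9 of 12 cases and lower in 2 (median 1.15, 1.0 to 2.08 over the 4 scalings, camera adjusted p = 0.0246, and adjusted p = 0.262 with an estimated correlation); adjusted over the list alone, 9 were higher and 2 lower. Smooth muscle myosin (Myh11) had 3.02 ± 0.16 and Lmod1 2.35 ± 0.13. Oxidative phosphorylation genes were higher in 33 of 74 cases and lower in 7 (median 0.33, 0.27 to 1.36 over the 4 scalings, camera adjusted p = 0.00775, and adjusted p = 0.391 with an estimated correlation); adjusted over the list alone, 32 were higher and 6 lower. The ATP synthase subunit gene Atp5g2 had 1.84 ± 0.17 and the cytochrome c oxidase subunit gene Cox7a2 1.75 ± 0.16. Ribosomal proteins, not called here (median 0.11, 0.11 to 1.43 over the 4 scalings, camera adjusted p = 0.0855), were called up with median centring (median 1.43, adjusted p = 5.71e-08).

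After doxorubicin 6770 genes differed, 3034 higher and 3736 lower in staggerer cells, of which 4101 differed at least 2-fold. Ppbp had 7.89 ± 0.16 and Igfbp2 4.0 ± 0.12, and Stmn2, a neuronal microtubule regulator, had 4.18 ± 0.15. Wfdc1 was at least 26.2-fold and the neuropeptide gene Vip at least 17.0-fold higher. Cxcl15 (6.15 ± 0.25), Col10a1 (4.67 ± 0.20), Galnt13 (4.37 ± 0.17) and Coch (4.09 ± 0.28) were higher too. Among lower genes, Ankk1 was lower by at least 10.6-fold, Kcne1l by at least 10.4-fold, Nudt10 by at least 6.93-fold, the endothelial matrix gene Mmrn2 by at least 6.31-fold, Fam181b by at least 4.44-fold and the inflammatory caspase gene Casp1 by at least 4.14-fold. Fam180a had -3.97 ± 0.32, Mdk -3.94 ± 0.11, the signalling gene Wnt4 -3.88 ± 0.57 (-2.63 by another probe) and Rcsd1 -3.82 ± 0.58. The share of differing genes that were higher was 44.8% with quantile normalization, 58.9% with median centring, where the median of all genes was 0.27, and 20% with no between-array normalization, where it was -0.81. In simulated data for this comparison, with far fewer changed genes than passed here, 23.9% of genes changed 1.5-fold, 65.7% changed 2-fold and 92.4% changed 4-fold were recovered among 9340 genes. They are not the power of the real test either. The genotype effects before and after treatment share no arrays; across genes their Pearson r was 0.333 and Spearman rho 0.262. Higher in both were 375 genes (201.1 for independent lists) and lower in both 364 (230.8), while 123 were higher before and lower after treatment (247.6) and 106 the opposite (187.4).

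Which responses differed between the genotypes was asked with the interaction of genotype and doxorubicin, the staggerer response minus the wild type response. By camera with the preset correlation, the response of the p53 target, immediate early, interferon and histone lists was shifted down in staggerer cells, with 20 of 31, 19 of 25, 14 of 21 and 25 of 39 genes lower. That of the matrix, contractile, cholesterol synthesis and DNA replication lists was shifted up, with 16 of 28, 7 of 12, 13 of 18 and 13 of 29 higher, though the DNA replication median was -0.06 with no between-array normalization. With an estimated correlation these had adjusted p-values from 0.181 to 0.374. For Mdm2 the difference in response was -2.56 ± 0.20 (adjusted p = 0.000177), for Cdkn1a -2.49 ± 0.19 (adjusted p = 0.000177), for Bbc3 -2.55 ± 0.27 (adjusted p = 0.000333), for Pmaip1 -1.37 ± 0.20 (adjusted p = 0.00111) and for Usp7 -0.82 ± 0.25 (adjusted p = 0.0226). Rora, undetected in treated staggerer cells, did not pass (adjusted p = 0.427), and the Bbc3 probe detected on only 3 of the 8 arrays gave -0.35. The staggerer doxorubicin arrays that enter each of these had a median signal of 7.60 ± 0.07 (SD, n = 2). Genes of like level were compared only for the p53 targets and immediate early genes. A part played by level of expression stays open for the other lists.

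**Figure D3:**
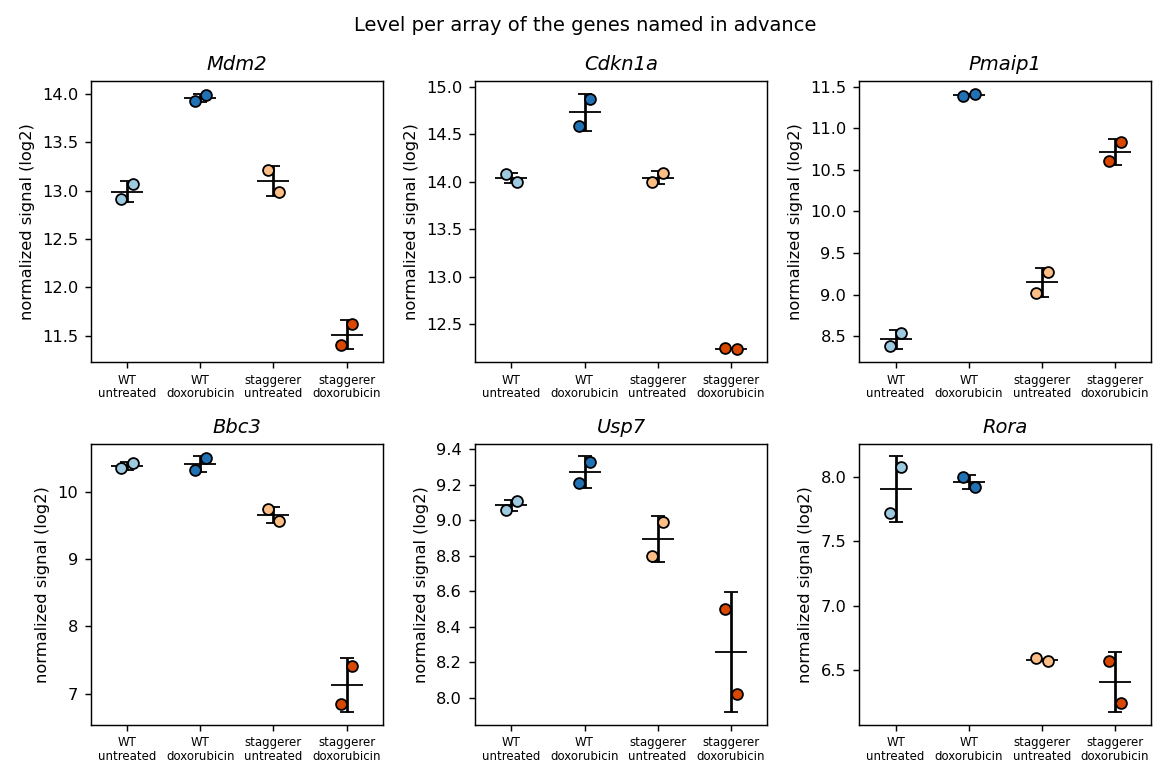
Normalized log2 signal of 6 genes on each array (points), with the group mean and SD (n = 2) as bars, in the 4 groups. Mdm2 was 12.99 and 13.96 in wild type cells without and with doxorubicin, and 13.10 and 11.51 in staggerer cells.

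Mdm2 had a level of 12.99 ± 0.11 (SD, n = 2) in untreated wild type cells, 13.96 ± 0.04 in treated wild type cells, 13.10 ± 0.16 in untreated staggerer cells and 11.51 ± 0.15 in treated staggerer cells. Cdkn1a had 14.04 ± 0.05, 14.73 ± 0.20, 14.04 ± 0.07 and 12.24 ± 0.00484 in the same order, Bbc3 10.39 ± 0.06, 10.41 ± 0.12, 9.65 ± 0.12 and 7.13 ± 0.40, and Pmaip1 8.46 ± 0.12, 11.40 ± 0.01, 9.15 ± 0.18 and 10.72 ± 0.16. Of 31 p53 targets 20 had a lower response in staggerer cells, 0 a higher one and 11 did not pass (median -1.29, -1.73 to -0.93 over the 4 scalings, or -1.03 with undetected members at their bound; camera adjusted p = 0.00016, and adjusted p = 0.181 with an estimated correlation); adjusted over the list alone, 21 were lower. Fas had -2.60 ± 0.20 and Trp53inp1, a p53-induced stress protein gene, -2.30 ± 0.18 (-1.28 by another probe). Of the 9 with apoptotic functions 6 were lower and 0 higher (median -1.37, -1.73 to -1.01 over the 4 scalings, camera adjusted p = 0.0344, and adjusted p = 0.386 with an estimated correlation); adjusted over the list alone, 6 were lower and 1 higher. Immediate early genes had a lower response in 19 of 25 cases and a higher one in 1 (median -1.46, -1.66 to -0.91 over the 4 scalings, or -0.98 with undetected members at their bound; camera adjusted p = 0.00016, and adjusted p = 0.181 with an estimated correlation); adjusted over the list alone, 20 were lower and 1 higher. Dusp1 had -2.26 ± 0.17 and Junb -2.17 ± 0.16. Histone genes were lower in response in 25 of 39 cases and higher in 0 (median -0.74, -1.05 to -0.33 over the 4 scalings, camera adjusted p = 0.0021, and adjusted p = 0.374 with an estimated correlation); adjusted over the list alone, 26 were lower. H3c6 had -1.72 ± 0.19 and H4c8 -1.67 ± 0.16. Interferon response genes were lower in 14 of 21 cases and higher in 1 (median -1.09, -1.33 to -0.50 over the 4 scalings, or -0.82 with undetected members at their bound; camera adjusted p = 0.0111, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 14 were lower and 1 higher. Ifi35 had -2.39 ± 0.21 and Ifit3 -2.02 ± 0.16 (-0.95 by another probe). The clock list, not called here (median -0.99, -1.67 to -0.68 over the 4 scalings, camera adjusted p = 0.0615), was called down without background correction (adjusted p = 0.0483) and with median centring (adjusted p = 0.0186).

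Extracellular matrix genes had a higher response in staggerer cells in 16 of 28 cases and a lower one in 0 (median 0.70, 0.64 to 1.56 over the 4 scalings, camera adjusted p = 0.000202, and adjusted p = 0.181 with an estimated correlation); adjusted over the list alone, 16 were higher. Mfap5 had 3.35 ± 0.18 and Mfap2 1.77 ± 0.16. Contractile genes were higher in 7 of 12 cases and lower in 1 (median 1.13, 0.88 to 1.87 over the 4 scalings, camera adjusted p = 0.0083, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 9 were higher and 1 lower. Mylk had 3.29 ± 0.23 and Lmod1 1.79 ± 0.18. DNA replication genes were higher in 13 of 29 cases and lower in 1 (median 0.56, -0.06 to 0.66 over the 4 scalings; camera adjusted p = 0.00912, and adjusted p = 0.32 with an estimated correlation); adjusted over the list alone, 13 were higher and 1 lower. The helicase gene Mcm2 had 2.38 ± 0.16 and Rrm1 2.22 ± 0.16. Cholesterol synthesis genes were higher in 13 of 18 cases and lower in 3 (median 1.01, 0.52 to 1.24 over the 4 scalings, camera adjusted p = 0.00948, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 13 were higher and 3 lower. Sc5d, a late enzyme of the pathway, had 2.10 ± 0.19, and Hmgcs1 was among those lower (-1.46 ± 0.16). Oxidative phosphorylation genes were higher in 24 of 74 cases and lower in 6 (median 0.25, 0.24 to 1.28 over the 4 scalings, camera adjusted p = 0.0111, and adjusted p = 0.391 with an estimated correlation); adjusted over the list alone, 22 were higher and 5 lower. Ndufb5 had 2.13 ± 0.25 and Cox7a2 1.83 ± 0.23. Ribosomal protein genes were higher in 14 of 58 cases and lower in 2 (median 0.25, 0.24 to 1.44 over the 4 scalings, camera adjusted p = 0.0142, and adjusted p = 0.314 with an estimated correlation); adjusted over the list alone, 9 were higher and 2 lower. The share of higher ones was no larger than among all genes (2480 of 9340), while the share of lower ones was smaller (3039 of 9340 among all). Rpl22l1, a ribosomal protein paralog, had 3.29 ± 0.32. The 2 lower members were Rps19bp1 (-2.05 ± 0.17) and Rps6ka5, which were matched by name and are not ribosomal protein genes. Macrophage markers were higher in 4 of 6 cases and lower in 0 (median 0.88, 0.56 to 1.36 over the 4 scalings, or 0.77 with undetected members at their bound; camera adjusted p = 0.0294, and adjusted p = 0.251 with an estimated correlation); adjusted over the list alone, 5 were higher. Fcer1g had 1.59 ± 0.20 and the leukocyte tetraspanin gene Cd53 1.84 ± 0.31. The macrophage call was lost without background correction (median 0.56, adjusted p = 0.0661), with median centring (median 1.36, adjusted p = 0.0676) and with no between-array normalization (median 0.65, adjusted p = 0.056).

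**Figure D4:**
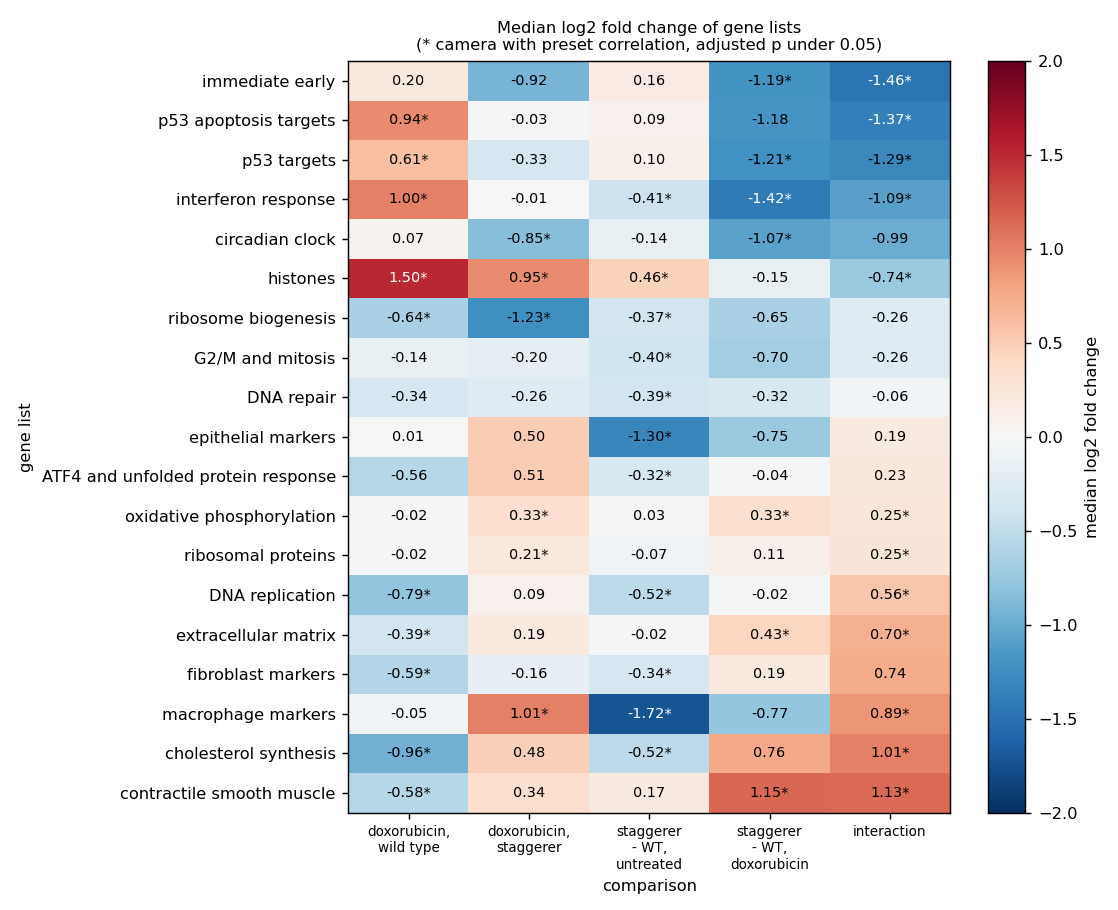
Median log2 fold change of the 19 gene lists called in any of the 5 comparisons, as colour and number, with an asterisk where camera with the preset correlation gave an adjusted p under 0.05. The p53 targets have 0.61 in wild type cells after doxorubicin, -0.33 in staggerer cells and -1.29 in the interaction; with an estimated correlation 0 lists were called in any comparison.

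The interaction passed for 5519 genes, 2480 with a higher and 3039 with a lower response in staggerer cells, of which 3801 differed at least 2-fold. The 10 largest higher responses were those of Mfap5, Mylk and Rpl22l1, given above, and of Angptl7 (4.59 ± 0.27, adjusted p = 0.000152), the transcription factor gene Nfib (3.79 ± 0.24), Prss35 (3.53 ± 0.21), the RNA-binding protein gene Rbms3 (3.40 ± 0.18), the spliceosomal RNA gene Rnu6 (3.35 ± 0.16), Aldh1a7 (3.32 ± 0.37) and Dtd1 (3.22 ± 0.31). The largest lower responses were all of genes undetected in some group, so their size depends on the background: Fam181b (-4.60 ± 0.29), Sytl1 (-4.5 ± 0.20), Mmrn2 (-4.38 ± 0.23), Nudt10 (-3.98 ± 0.35), the sodium channel subunit gene Scn3b (-3.96 ± 0.15, or -2.47 by another probe), Gal3st1 (-3.87 ± 0.44), the nuclear receptor coactivator gene Ncoa1 (-3.84 ± 0.33), Pid1 (-3.69 ± 0.40), Ankk1 (-3.67 ± 0.22) and Kcne1l (-3.65 ± 0.35). The share of these genes with a higher response was 44.9% with quantile normalization, 60.5% with median centring, where the median of all genes was 0.28, and 28.5% with no between-array normalization, where it was -0.43. In simulated data for this comparison, 0% of genes changed 1.5-fold, 31.3% of those changed 2-fold and 84.8% of those changed 4-fold were recovered among 9340 genes. As far fewer genes were changed there than passed here, real changes of 1.5-fold may still be found.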

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

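All results here were listed because the interaction test found a different doxorubicin response in the 2 genotypes. Of the tests of explanations, that of between-array scaling, that of short-lived transcripts and both on array signal were chosen after the result was seen; the test matched on expression level was not.

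The interaction passed for 5519 genes. The 12 lists below were called by camera with the preset correlation, and 0 of them with an estimated one (adjusted p from 0.181 to 0.391). The difference in response (staggerer minus wild type, log2 median over a list) was -1.29 for p53 targets, -1.37 for p53 targets with apoptotic functions, -1.46 for immediate early genes, -1.09 for interferon response genes and -0.741 for histones. It was 0.557 for DNA replication, 1.01 for cholesterol synthesis, 0.704 for extracellular matrix, 1.13 for contractile genes, 0.252 for ribosomal proteins, 0.247 for oxidative phosphorylation and 0.885 for macrophage markers. With members undetected in a group at their bound, the median was -1.03 for p53 targets, -0.976 for immediate early genes, -0.82 for interferon response genes and 0.767 for macrophage markers. Over quantile normalization, no background correction, median centring and no between-array normalization, the medians of the lists with a lower response ran from -1.73 to -0.927 for p53 targets, -1.73 to -1.01 for p53 targets with apoptotic functions, -1.66 to -0.91 for immediate early genes, -1.33 to -0.499 for interferon response genes and -1.05 to -0.334 for histones. Those of the others ran from -0.0566 to 0.658 for DNA replication, 0.523 to 1.24 for cholesterol synthesis, 0.639 to 1.56 for extracellular matrix, 0.879 to 1.87 for contractile genes, 0.243 to 1.44 for ribosomal proteins, 0.245 to 1.28 for oxidative phosphorylation and 0.564 to 1.36 for macrophage markers. In the p53 pathway, the difference was -2.56 for Mdm2, -2.49 for Cdkn1a, -2.55 for Bbc3, -1.37 for Pmaip1, -0.82 for Usp7, -2.60 for Fas and -2.30 for Trp53inp1, while other probes gave -0.35 for Bbc3 and -1.28 for Trp53inp1. In other lists with a lower response it was -2.26 for Dusp1, -2.17 for Junb, -2.39 for Ifi35, -2.02 for Ifit3, -1.72 for H3c6 and -1.67 for H4c8. In lists with a higher response it was 3.35 for Mfap5, 1.77 for Mfap2, 3.29 for Mylk, 1.79 for Lmod1, 2.38 for Mcm2, 2.22 for Rrm1, 2.10 for Sc5d, 2.13 for Ndufb5, 1.83 for Cox7a2, 3.29 for Rpl22l1, 1.59 for Fcer1g and 1.84 for Cd53, with the members Hmgcs1 at -1.46 and Rps19bp1 at -2.05. Among single genes it was 4.59 for Angptl7, 3.79 for Nfib, 3.53 for Prss35, 3.40 for Rbms3, 3.35 for Rnu6, 3.32 for Aldh1a7 and 3.22 for Dtd1. For genes undetected in some group it was -4.60 for Fam181b, -4.5 for Sytl1, -4.38 for Mmrn2, -3.98 for Nudt10, -3.96 for Scn3b, -3.87 for Gal3st1, -3.84 for Ncoa1, -3.69 for Pid1, -3.67 for Ankk1 and -3.65 for Kcne1l.

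Of 31 p53 targets, 22 rose in wild type cells, 20 had a lower response in staggerer cells and 15 did both, while the list was not called with an estimated correlation (camera adjusted p = 0.181). Among all genes, 1541 of the 2465 that rose in wild type cells also had a lower response, so doing both was not particular to p53 targets. The wild type response is part of the interaction, which favours such an overlap. Between-array scaling is argued against, since the p53 targets' median interaction minus that of all genes was -1.18 (SE 0.204 over 31 genes) with quantile normalization and -1.29 with median centring, which equals no between-array normalization by construction here. Without background correction it was -0.871. A loss of signal at their level of expression is argued against too, since against the 100 genes nearest in untreated level it was -1.03 (SE 0.216). A general loss of short-lived transcripts in the treated staggerer cells stays open, since immediate early genes matched in the same way had -1.3 (SE 0.224 over 25 genes). A genotype-dependent p53 response may therefore be only part of the pattern, and the difference by genotype that the design names stays open.

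The staggerer doxorubicin arrays had a lower median signal. A uniform loss of brightness is argued against, since the 99th percentile was higher than on the untreated staggerer arrays by 0.298 (SE 0.0358 over 4 arrays), while the median was lower (-1.02). A few genes taking more of the signal stays open as a candidate explanation. The brightest 1% of probes took 6.11 percentage points more of the summed signal (SE 0.0927). That share was 27.3% ± 0.0725 (SD, n = 2) against 21.2% ± 0.109 in untreated staggerer cells. A lower median beside a higher 99th percentile nearly fixes a larger share in advance. The share therefore cannot tell a gain of bright genes from a loss of RNA from most genes. A loss of RNA from most genes in these cells, and differences in RNA quality, were not tested.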

How the results depend on the processing

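Of 4026 recomputed values for 215 named pairs of gene and comparison, 3949 kept their direction and side of the threshold, 63 became weaker, 1 stronger and 13 turned. The added alternatives (no between-array normalization, leaving out both staggerer doxorubicin arrays, detection in a compared group) were chosen after seeing the data. None of the gene values and p53 medians that turned had passed the test; the cause was not tested. With no between-array normalization these were, in wild type cells, Bbc3 (-0.253), Rora (-0.251) and Usp7 (-0.112), and in untreated cells Cdkn1a (-0.255), Mdm2 (-0.207) and the median of the p53 targets (-0.238). With median centring they were Rora, undetected in treated staggerer cells, in those cells (0.284) and in the interaction (0.225), and the p53 median in staggerer cells (0.0108). With the mean of a gene's probes Bbc3 in wild type cells had -0.0177. Over the fits that left out an array, Bbc3 in wild type cells reached from -0.0570 to 0.107, Rora in wild type cells from -0.123 to 0.236 and Cdkn1a in untreated cells from -0.0413 to 0.0526, with Bbc3 also at -0.0181 and Cdkn1a at -0.0319. With 1 array left in a group, the lone array is assumed to vary like the other groups.

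With an estimated correlation the p53 medians of 0.607 in wild type cells, -1.21 after doxorubicin and -1.29 in the interaction no longer passed (adjusted p = 0.181 each), and 0 gene lists were called in each of the 5 comparisons. With 4 residual degrees of freedom, that test cannot tell an absent shift from a lack of power. The number of genes that differed before treatment was 793 with no detection filter and 2543 with no between-array normalization, and leaving out an array gave 518 to 1651 (1196 in full); fewer arrays raise the standard error, while the cause of the other changes was not tested. Detection on all arrays left 7 lists before and 4 after treatment. The ranges over fits without an array were 3952 to 5833 genes in wild type cells, 5104 to 5944 in staggerer cells, 5787 to 6730 between treated genotypes and 4595 to 5721 for the interaction; the p53 medians were 0.6 to 0.719, -0.356 to -0.254, -1.24 to -1.03 and -1.31 to -1.04 in the same order, and 0.0604 to 0.125 before treatment. The labels number the replicates alike in each group, but the deviations of arrays with the same number correlated between -0.0328 and 0.0255, so they share only a number. With the replicate block the counts were 5148, 5991, 1038, 6706 and 5404, with 10, 6, 11, 7 and 12 lists. Without the staggerer doxorubicin arrays 5776 genes changed in wild type cells and 1583 differed before treatment. Fitting only the 4 arrays compared gave 5807 changed genes in wild type and 5372 in staggerer cells, with 1558 differing before and 6232 after treatment. The full counts were 5304, 6072, 1196 and 6770. Fewer arrays can lower a count, but the rises came despite them. The median absolute replicate difference was 0.221 in treated staggerer cells and 0.142 to 0.143 in the other groups. The shared spread may be too small for comparisons with that group and too large for the others. Of 46 calls of a list in a comparison, 45 kept the sign of their median under the 4 scalings. The other was DNA replication in the interaction, which had passed and whose median of 0.557 became -0.0566 with no between-array normalization. Signal over background limits the staggerer doxorubicin comparisons: of the changed genes 168 were below background in both groups there, and 838 fell to below background. The series matrix was not run, being identical to the authors' table, and the slide was not run, as no slide is named.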

Other observations

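Of the tests below, the one on further mesothelial genes and the one on scaling were chosen after the result was seen, and the genes named here were chosen after their values were seen or are all tested members of a list.

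Of the 9 gene lists called in no comparison, the oxidative stress genes driven by NRF2 came closest, with a median of 0.64 in staggerer cells after doxorubicin (0.27 to 1.29 over the 4 scalings, 14 genes, camera adjusted p = 0.0722). They were called there without background correction (adjusted p = 0.0434) and with no between-array normalization (adjusted p = 0.014). The ROR-linked lipid metabolism genes had medians from -0.51 in wild type cells after doxorubicin (-0.30 with undetected members at their bound, -0.74 to -0.32 over the scalings) to 0.88 in the interaction (0.49 to 1.21 over the scalings; 10 genes, smallest camera adjusted p = 0.191). The smallest adjusted p of the 8 genes neighbouring Rora was 0.508, with fitted medians from -0.29 to 0.19, or -0.83 to 0.41 over the scalings. It was 0.38 for 19 NF-kB and inflammatory genes, 0.635 for 11 Wnt targets, 0.798 for 9 heat shock genes, 0.101 for 11 imprinted genes, 0.439 for 22 Hox genes and 0.34 for 5 cartilage and bone markers. The imprinted genes were called down in untreated staggerer cells without background correction (adjusted p = 0.04), and up with median centring in staggerer cells after doxorubicin (adjusted p = 0.0314) and in the interaction (adjusted p = 0.0372). Lists with under 5 tested members were not tested as lists. Among adipocyte markers in untreated cells, the adipogenic receptor gene Pparg was higher (1.89, adjusted p = 0.000154) and lipoprotein lipase, Lpl, lower (-1.87, adjusted p = 0.000158) in staggerer cells, while Cebpa was undetected in both genotypes. With doxorubicin Cebpa was at least 3.4-fold higher in wild type cells (adjusted p = 3.91e-05) and stayed undetected in staggerer cells, and the interaction passed (adjusted p = 0.000283).

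Within the histones, the families moved apart, a division made after their values were seen. After doxorubicin in wild type cells 10 of 10 H2B genes, 6 of 6 H3 genes and 7 of 9 H4 genes rose and 0 fell, while of 13 H2A genes 8 fell and 4 rose (median -0.76). In staggerer cells 9 H2B, 4 H3 and 8 H4 genes rose and 0 fell, and of the H2A genes 8 fell and 4 rose (median -1.44, -2.29 to -1.23 over the 4 scalings). The H2A genes that fell were, in both genotypes, H2ac7, H2ac10, H2ac11, H2ac12, H2ac15, H2ac20, H2ac22 and H2ac24. Each family median kept its sign under all 4 scalings in both comparisons. Histone genes of a family are nearly identical in sequence, so a probe can read several of them and the count of genes is uncertain.

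Some members moved against their list. In wild type cells after doxorubicin, the DNA replication genes E2f1, Cdc45, Rrm2 and Chaf1b rose, as did Hsd17b7 of cholesterol synthesis, while Irf9 and Ifit2 of the interferon response fell. In staggerer cells Ncl and Bop1 of ribosome biogenesis rose and Rps15a fell. In untreated staggerer cells the repair gene Xpa and the epithelial marker Trp63 were higher; beside Fas and Pmaip1, the p53 target that was higher there was Ephx1. After doxorubicin the p53 target and death receptor gene Tnfrsf10b (1.33), the immediate early gene Maff (0.57) and the interferon genes Zbp1 and Ifit2 were higher in staggerer cells, and the matrix genes Mfap4, Dcn, Thbs2 and Eln and the contractile genes Smtn and Des were lower. In the interaction, Maff and Bst2 were higher and Cdc45, Smtn, Sqle, Hsd17b7 and Rps6ka5 lower.

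The haemoglobin gene Hba-a1, the tested erythroid marker, was at least 3.59-fold higher after doxorubicin in wild type cells (adjusted p = 1.84e-05) and undetected in the other 3 groups, and its interaction passed (adjusted p = 0.000289). Skeletal muscle actin, Acta1, had an interaction of 2.12 (adjusted p = 0.000345). Of 4 endothelial markers, Emcn was at least 2.63-fold lower in untreated staggerer cells (adjusted p = 0.000104) and Esam at least 1.47-fold higher (adjusted p = 0.0273), while Egfl7 (-0.42) and Eng (-0.32) did not pass. Of 3 neural and glial markers, Mbp was lower there (-1.30, adjusted p = 0.0018), and Ncam1 (0.02) and Nes (-0.20) did not pass. Of the sex-linked genes, Xist and Uty had -0.38 and 0.24 in untreated cells and did not pass; after doxorubicin they were higher in staggerer cells by 0.95 and 0.89. Another Xist probe, detected on 8 arrays, stayed between 7.67 and 8.47. Uty lay at a low level, between 6.01 and 7.05, and the Y-linked genes Eif2s3y and Kdm5d were detected on 0 arrays.

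In untreated staggerer cells 4 of 6 macrophage and 4 of 6 epithelial markers were lower, and 1 epithelial marker, Trp63, was at least 1.43-fold higher. The epithelial median of -1.30 was -0.737 with members at their bounds, and neither list was called with an estimated correlation (adjusted p = 0.181 and 0.264). Between-array scaling is argued against, since their median minus that of all genes was -1.35 (SE 0.526 over 12 genes) at whichever of quantile normalization, median centring and no between-array normalization was nearest 0. That SE counts genes as independent, which they are not, so it may be too small. Without background correction the medians of the 2 lists relative to all genes were -1.37 and -0.507. A candidate explanation that stays open is fewer macrophages in the staggerer cultures: of 16 further macrophage genes tested, 16 were lower and 0 higher (median -1.62, or -1.13 with undetected members at their bound). Among them C1qb was at 9.03 ± 0.06 (SD, n = 2) in wild type and 6.53 ± 0.27 in staggerer cells. The abundant gene Lyz2, at 11.99 ± 0.03 and 9.93 ± 0.01, belongs to the marker list that gave the pattern and is no further evidence. Of 30 further macrophage genes listed, 16 passed the detection filter, and 10 of these were undetected on both arrays of an untreated group. A gene that passed only through wild type arrays could hardly come out higher in staggerer cells, so the filter partly set this count. The further genes detected on all 8 arrays were lower as well: C1qc (-2.40), Cd14 (-0.97), Coro1a (-1.06) and Ctsc (-1.20). Fewer mesothelial cells may add to the pattern, since of 6 further mesothelial genes 3 were lower and 0 higher (median -0.77), at the lower limit set for that test, with Bnc1 at 8.24 ± 0.00151 in wild type cells and undetected in staggerer cells. After doxorubicin fewer of these genes were lower. Of the further macrophage genes 10 were lower and 2 higher (median -0.73, or -0.10 with undetected members at their bound). The macrophage markers were not called (camera adjusted p = 0.481). As 9 of the 16 were undetected on both arrays of a treated group, whether the deficit itself weakened stays open. The macrophage interaction, called with quantile normalization, was lost under each other scaling and with an estimated correlation. Of the further mesothelial genes 2 were lower and 2 higher. Bnc1, detected on 2 of 2 treated staggerer arrays, was still lower there (-2.38, limma adjusted p = 9.43e-06). Fibroblasts can express some of the macrophage and mesothelial genes, and a change of expression within fibroblasts, or a difference by genotype, stays open.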
